A study of Mus musculus with 6 samples.

How the data were processed

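RNA was measured by bulk RNA sequencing in 6 libraries of group 1 innate lymphoid cells (ILC1s) from mouse liver, 3 naive and 3 memory. Per the labels' protocols, total RNA was taken up in TRIzol and libraries were made with a stranded mRNA kit. The sort or gate that gave the cells is not given in the sources used here. A single table of gene values was analysed, deposited as RPKM (assigned reads scaled by exon length and by the library's total). The submitters' processing notes name STAR 2.5.3a, featureCounts, Subread 1.5.1, edgeR 3.12.1 and the build mm10, without saying which step used which. Per the file headers, each of the 23942 genes has a position, a strand and an exon length. The strand setting of the counting, the annotation release and any use of molecular identifiers are not given in the sources used here, so reads of overlapping genes, antisense partners and near-identical copies could have been shared or lost.

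Groups and replicate numbers came from the labels. Each value times the exon length in kilobases summed to the same total in every library, so the values were scaled by each library's total of assigned reads. The step per read was estimated in each library from its smallest values and refined over larger ones. Dividing by that step gave whole reads for 100% of values, within 0.001 of a read. The recovered totals were 18697093, 20340486 and 21131528 reads for naive replicates 1 to 3, and 21244953, 23795266 and 19849507 for memory replicates 1 to 3. Among genes with 1 to 10 reads, 69.8% to 72.3% of counts were even, a pattern that arises when both mates of a pair are counted, so the number of independent molecules was lower than the number of reads. Floors of 3 reads cover counting error only. At 1 kilobase of exon that floor was 0.126 to 0.16 RPKM. By symbol, 23015 genes matched GENCODE M21, 23007 of them at an overlapping position, and 8 symbols had been turned into dates.

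The values being RPKM, the main test was limma-trend (limma 3.58.1 in R 4.3.3) on log2(RPKM + 1), for genes with a mean of at least 0.5 RPKM over the 6 libraries, with Benjamini-Hochberg adjustment over the 13793 genes tested and a threshold of 0.05. "Called" means past that threshold. Fold changes are memory minus naive on the log2(RPKM + 1) scale, which understates the change of low genes. Every adjusted p printed for a gene comes from limma. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical. No replicate block was used.

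Before use, the test was run on counts simulated from the real means and totals of this comparison with 13786 genes tested. It recovered 40.4% of 99 genes changed 1.5-fold and 69.4% of 98 genes changed 2-fold. Among genes of at least 2 RPKM those shares were 51.3% and 84.0%. Of 13589 unchanged genes, 10 were called. Every simulated gene had the same dispersion (0.00129), which leaves out differences in spread between real genes, so these results may be too favourable.

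A set of 32 gene lists was fixed before the data were examined, along with the tests, the panel of 12 genes and the other choices not said to have come later. Each list was summarised by its called members, by the calls adjusted over the list alone, and by limma's camera with a preset correlation of 0.01, adjusted over the 31 lists with more than 1 tested member. Camera with an estimated correlation was the check, and fry was run beside it. Genes to name were drawn from the panel, the 10 largest called rises and falls among named genes with non-overlapping groups and at least 1 RPKM in the higher group, and up to 4 members per list with the smallest adjusted p. Up to 2 members with the highest level were added for lists of other cell types. Ncr1, Klrb1c, Itga4, Klra9, Dusp5, Hspd1, Rn7sk and the extra genes of the closing section were chosen after their values were seen. Lists and tests chosen later are named as such where they appear.

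The alternatives were other pseudocounts (0.1 and 0.5), no filter, a filter of 2 RPKM, quantile normalization, median ratio scaling, a robust prior, array weights, the replicate number as a block, an added fold threshold, limma's voom on the recovered reads, and each library left out in turn. Restriction to protein coding genes, and removal of the lists of other cell types, were added after seeing the data. Figures and permutation tests used Python 3.11.15 with scipy 1.17.1 and matplotlib 3.10.9. Some listed genes, among them Cd3e and Il17a, were not analysed here, and 40 genes that the naming rule picked are not reported here.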

Results

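Gene expression was measured in naive ILC1s (3 libraries, solvent, day 0) and memory ILC1s (3 libraries, treatment labelled OXA, day 30) from mouse liver. ILC1s are tissue-resident lymphocytes related to natural killer (NK) cells that make interferon-gamma. The labels do not spell out OXA. The recovered depth was 18697093 to 23795266 reads per library, and 18571 to 19349 genes had at least 1 read. Replicates of a group correlated at 0.988 to 0.990 (Pearson, across genes, log2 scale), against 0.982 to 0.985 between groups. No 2 libraries agreed within the counting noise of independent reads (chi-square per gene at least 4.93, and at least 2.47 with reads halved, as if both mates of every pair had been counted), and all 6 were kept as labelled. Copies of molecules made during amplification would add to these values. The median coefficient of variation was 4.85% in naive and 4.61% in memory libraries over 4950 genes of at least 10 RPKM. The first principal component held 43.7% of the variance and separated the groups.

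The comparison asks how memory ILC1s differ from naive ILC1s. Treatment and day differ together between the groups, and none of the 6 libraries is solvent at day 30. Effects of treatment, elapsed time and any batch that follows the groups therefore cannot be told apart. Memory libraries held more RNA of macrophage, monocyte and MHC class II genes, of cholesterol synthesis genes and of the granzyme gene Gzmc. The hepatocyte list was also higher, but its called members Apoe and Hp are expressed by macrophages and monocytes too. Memory libraries held less RNA of cell cycle genes and of the T cell receptor gamma gene Tcrg-C1, and far less of 7S RNA and RNase P RNA. The immediate early and interferon-stimulated lists were higher and the heat shock list lower by camera at a preset correlation, but not with an estimated correlation (adjusted p = 0.0513, 0.0513 and 0.156). Of 25 tested ILC1 signature genes, 19 were not called. Of 13793 genes tested, 575 were called, 441 higher and 134 lower in memory, and in all 575 the groups did not overlap. Non-overlapping groups were seen in 24.1% of tested genes, where chance gives 10%. The count was 358, 308 and 387 without naive replicate 1, 2 or 3, and 339, 275 and 321 without memory replicate 1, 2 or 3. It was 1141 with voom on the recovered reads, of which 523 were among the 575, and 181 with an added absolute log2 fold change of at least 1.

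Among the fixed panel, Rora, the gene of the nuclear receptor in the study's title (chromosome 9, 68653786 to 69388246, mm10), was at 6.86 ± 0.55 RPKM in naive and 8.29 ± 0.59 in memory libraries (SD, n = 3 each), a log2 change of 0.24 (SE 0.08) that was not called (limma adjusted p = 0.179). Voom on the recovered reads called it (adjusted p = 0.00644, range over the alternatives 0.00644 to 0.39). Tbx21, the T-box factor of the lineage, was at 72.1 and 71.8 RPKM, and Eomes, the T-box factor of NK cells, at 0.81 and 1.19. The receptor gene Il7r was at 60.9 and 66.1, the integrin gene Itga1 (CD49a) at 35.8 and 33.6, Itga2 (CD49b) at 5.92 and 6.04, and Tnfsf10 (TRAIL) at 36.8 and 34.3. Zfp683 (Hobit) was at 105 and 97.2, Tcf7 at 44.9 and 42.9, and Ifng, the gene of interferon-gamma, at 19.4 and 22.6. None of these 9 was called, with adjusted p from 0.176 to 0.98. Ncr1, the gene of the activating receptor NKp46, was at 488 and 505 and Klrb1c (NK1.1) at 133 and 131, neither called. Cxcr6, the chemokine receptor that holds lymphocytes in liver sinusoids, fell from 58.8 to 48.0 (log2 change -0.29, SE 0.04, adjusted p = 0.0144). That call was lost without naive replicate 1 or 2 or memory replicate 1 or 3 (adjusted p up to 0.0648).

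**Figure D1:**
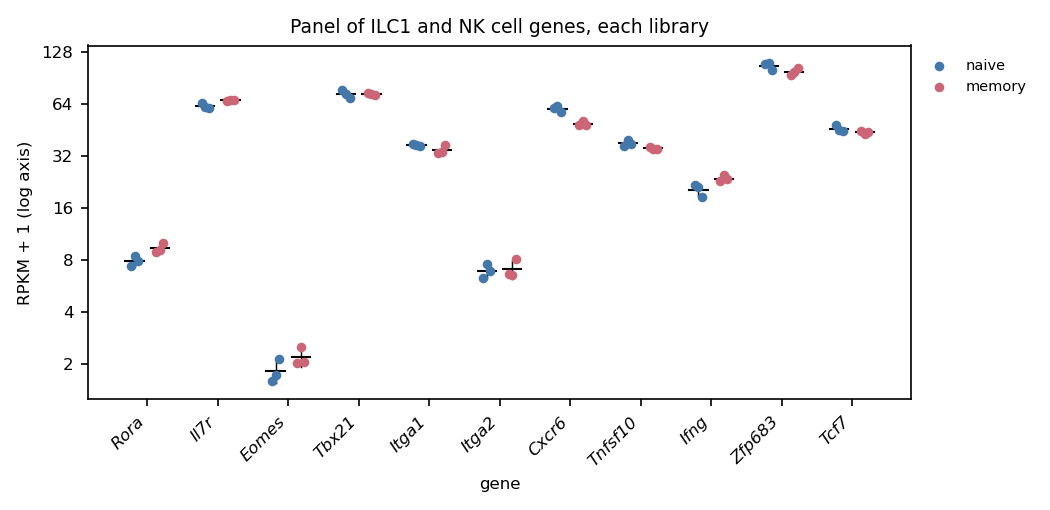
RPKM + 1 on a log axis of 11 panel genes in each library, with naive libraries in blue and memory libraries in red. Horizontal bars are means of 3 libraries and vertical bars 1 SD, and of these 11 only Cxcr6 (58.8 against 48.0 RPKM) was called.

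The ILC1 signature split. Of its 25 tested members, Gzmc, Ltb, Mmp9 and Ikzf2 rose, Cxcr6 and Cd3g fell and 19 were not called. Adjusted over the list alone, 8 were higher and 2 lower. Gzmc, which encodes granzyme C, a protease of cytotoxic granules (chromosome 14, 56231401 to 56234656), rose from 195 ± 7.36 to 372 ± 10.4 RPKM (log2 change 0.93, SE 0.04, adjusted p = 5.48e-05). Granzyme genes are close relatives, so some reads may be shared between them. Gzmb was at 884 and 806 RPKM and Gzma at 161 and 127, neither called (adjusted p = 0.116 and 0.0607). Besides Gzmc, the lysosomal membrane gene Lamp1 rose (26.1 to 34.9), and the other 11 of 13 cytotoxic granule genes were not called (2 higher and 2 lower adjusted over the list alone). Ltb, which encodes lymphotoxin beta, rose from 61.0 to 76.0 and Mmp9, a matrix protease, from 41.5 to 51.4. The signature as a set was not past camera's threshold (adjusted p = 0.486). Leaving out a library ended the calls of Ltb (naive 2, memory 1 or 3), Mmp9 (naive 2 or any memory library), Cd3g (any library but naive 3) and Ikzf2 (any library), with adjusted p up to 0.151.

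Genes of macrophages and monocytes rose together. Of 16 tested members of that list, 10 rose and none fell (12 and 0 adjusted over the list alone), and all 16 had a positive change, with a median of 0.87. Lyz2, which encodes the lysozyme of myeloid cells (chromosome 10, 117277334 to 117282274), rose from 37.8 ± 4.52 to 448 ± 14.1 RPKM (log2 change 3.54, SE 0.08, adjusted p = 6.94e-06). Csf1r, the receptor that macrophages need to survive, rose from 1.42 to 11.1, the scavenger receptor Marco from 1.18 to 7.01 and Adgre1 (F4/80) from 0.62 to 2.87. The most abundant member after Lyz2, Ccr2, a chemokine receptor of monocytes and lymphocytes, was at 66.2 and 67.9 and was not called. MHC class II genes moved with them. Of 13 tested members of the dendritic cell and MHC class II list, 8 rose and none fell (9 and 0 adjusted over the list alone). Cd74, the invariant chain, rose from 19.6 to 122 RPKM, H2-Ab1 from 20.2 to 134, H2-Eb1 from 7.8 to 62.5 and H2-Aa from 1.22 to 9.55. The integrin gene Itgax (CD11c) was at 79.9 and 76.8. The single tested neutrophil gene, Csf3r, rose from 0.17 to 1.55. By camera, the adjusted p was 1.52e-12 for the macrophage list and 9.01e-12 for the MHC class II list, and 0.0332 for each with an estimated correlation.

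Besides Lyz2, H2-Eb1 and H2-Ab1, the 10 largest named rises were Ccl6, a myeloid chemokine (1.99 to 23.4 RPKM), Cybb, a subunit of the phagocyte oxidase (2.32 to 23.8), Mpeg1 (perforin-2, 1.69 to 18.2), F13a1, a coagulation factor subunit made by monocytes (0.85 to 11.8), Ear2, an eosinophil-associated ribonuclease (1.28 to 13.9), Tgfbi (log2 change 2.64, to 11.4 RPKM in memory) and Mir7649. Their log2 changes were 2.64 to 3.54. Mir7649 had 0 to 2 reads in naive and 10 to 24 in memory libraries, and it lies within other annotated genes, so its value may be theirs. Lyz2 and Ear2 have close relatives that could share reads.

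**Figure D2:**
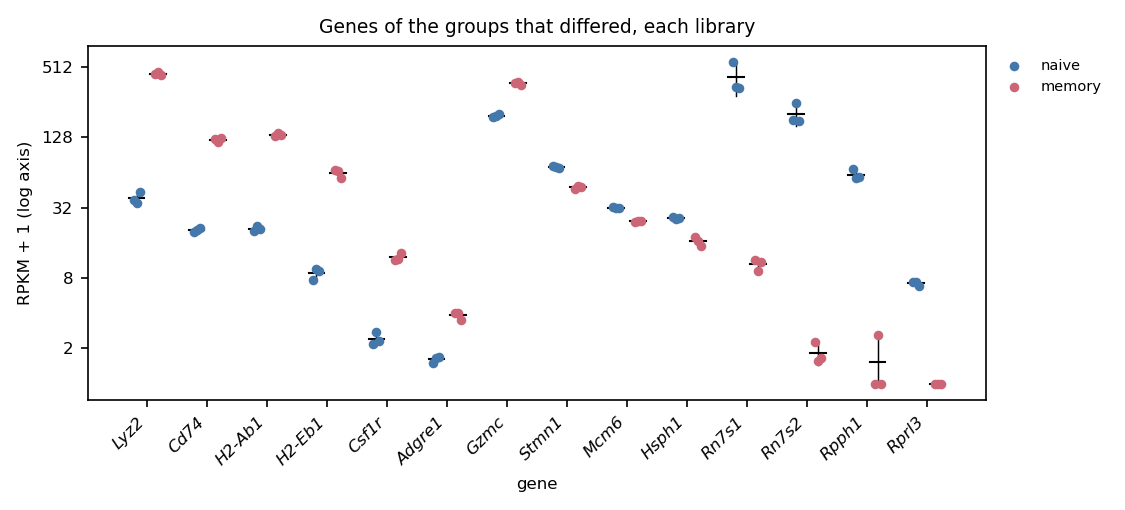
RPKM + 1 on a log axis of 14 genes in each library, with naive libraries in blue and memory libraries in red, bars as means of 3 libraries and 1 SD. Lyz2 stood at 37.8 RPKM in naive and 448 in memory libraries, and Rn7s1 at 418 and 9.57.

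NK cell markers changed in part. Of 19 tested members, 7 rose and 1, Klra9 (31.6 to 24.6 RPKM), fell, and adjusted over the list alone 7 were higher and 4 lower. Itgam (CD11b) rose from 6.06 to 15.9, Cx3cr1, the fractalkine receptor, from 0.67 to 5.56, and Zeb2, a factor of terminal differentiation, from 0.54 to 2.31. These 3 genes are also expressed by monocytes, whose list rose in the same libraries. The list as a set was not past the threshold by camera (adjusted p = 0.154), but was higher by fry (adjusted p = 0.000478). In the trafficking list of 19, 4 members rose, among them Cx3cr1, S1pr5 (1.07 to 2.85) and Itga4 (8.90 to 11.7), and Cxcr6 and Cxcr3 (60.4 to 50.3) fell (5 higher and 4 lower adjusted over the list alone, camera adjusted p = 0.799). Of 29 lymphoid transcription factors, Zeb2, Nr4a1 (2.03 to 5.64), Irf8 (17.5 to 21.4) and Ikzf2 (3.64 to 4.79) rose and none fell (5 and 0 adjusted over the list alone, camera adjusted p = 0.0776, and 0.038 without memory replicate 1). Like Zeb2, Nr4a1 is not particular to lymphocytes. It is also a member of the non-classical monocyte list of the closing section. That list was picked after these values were seen, so it adds no evidence on Nr4a1. Leaving out a library ended the calls of S1pr5 (naive 2 or any memory library), Irf8 (any but memory 3), Cxcr3 (naive 1 or 2, memory 2 or 3), Klra9 (memory 2 or 3) and Itga4 (any library), with adjusted p up to 0.123.

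Cytokine receptor genes were higher as a list. Of 23 tested, 7 rose and none fell (11 higher and 1 lower adjusted over the list alone). Csf2rb, the shared chain of the GM-CSF receptor, rose from 0.19 to 3.27 RPKM, Ifngr2 from 0.14 to 1.56 and Il6ra from 0.14 to 1.28. Monocytes express all of these, and the macrophage and monocyte list had a median change of 0.87. Il10ra, abundant already in naive libraries, rose from 45.5 to 55.3, a call lost without naive replicate 2 or memory replicate 1 or 2 (adjusted p up to 0.073). The list's camera adjusted p was 0.00016, and its adjusted p was 0.101 with an estimated correlation. Among 18 effector cytokine and chemokine genes, Ccl9, a myeloid chemokine (0.41 to 6.58), Ltb and Cxcl10 (0.56 to 1.92) rose and none fell (6 and 0 adjusted over the list alone). Cxcl10 was called only without memory replicate 1 among the fits that left out a library. The list's camera adjusted p was 0.00756, with an adjusted p of 0.324 for an estimated correlation and 0.0554 without naive replicate 3. In the inhibitory and activating receptor list, Havcr2 (TIM-3, also on myeloid cells) rose from 0.14 to 2.64 and Cd160 (189 to 166) and Klre1 (187 to 165) fell, among 22 tested (2 higher and 3 lower adjusted over the list alone). The list had a median of -0.06, a mean of 0.01 and camera lower in memory (adjusted p = 0.0171; adjusted p = 0.367 with an estimated correlation, 0.292 under quantile normalization and 0.0521 without naive replicate 1). The falls of Cd160 and Klre1 were lost under quantile normalization and in at least 5 of the 6 fits that left out a library.

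Immediate early genes, which cells transcribe within minutes of a stimulus, were higher in memory. Of 26 tested, 8 rose and 1, Dusp5 (28.4 to 22.8 RPKM), fell (12 and 2 adjusted over the list alone). Fos rose from 1.47 to 6.72, Junb from 53.0 to 72.4, Klf4 from 0.69 to 4.08 and Nfkbia, which encodes an inhibitor of NF-kB, from 30.9 to 54.1. Interferon-stimulated genes were also higher. Of 28 tested, 6 rose and none fell (11 and 0 adjusted over the list alone), and 26 had a positive change. Ifit3 rose from 17.6 to 26.2, Mx1 from 7.42 to 11.7 and Gbp3 from 43.1 to 56.7. Of 21 apoptosis and survival genes, Birc3 (18.7 to 26.6) and Pmaip1 (NOXA, 0.78 to 3.04) rose (5 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0776). The macrophage and monocyte list moved with all of these. In camera, adjusted p was 0.000275 for immediate early genes and 2.17e-06 for interferon-stimulated genes, each with an adjusted p of 0.0513 for an estimated correlation. The calls of Gbp3 (without naive 1, memory 1 or 3) and Dusp5 (without any library but memory 1) were lost, with adjusted p up to 0.103.

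Cell cycle genes were lower in memory. Of 39 tested, 11 fell and none rose (18 and 0 adjusted over the list alone), and 34 had a negative change, with a median of -0.20. Stmn1, which encodes a microtubule regulator of dividing cells, fell from 70.9 ± 1.63 to 46.8 ± 1.73 RPKM (log2 change -0.59, SE 0.04, adjusted p = 0.000555). Mcm3 fell from 41.3 to 30.9, Mcm6 from 30.9 to 23.4 and Mcm7 from 24.0 to 17.8. They encode subunits of the helicase that opens DNA for replication. Camera's adjusted p was 1.52e-12, and 0.0332 with an estimated correlation. The largest falls outside this list included Cdc6, the helicase loader (2.10 to 0.83), Chaf1a, a histone chaperone of replication (15.4 to 9.73), Uhrf1, which maintains DNA methylation (8.32 to 4.98), and Aunip (1.36 to 0.29), besides the ubiquitin ligase Dtx3l (log2 change -0.72). Leaving out a library ended the calls of Aunip (any library), Cdc6 (any but naive 3) and Uhrf1 (any naive library or memory 2), with adjusted p up to 0.149.

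Heat shock genes were lower as a list. Of 14 tested, 5 fell and none rose (2 higher and 6 lower adjusted over the list alone). Hsph1 fell from 25.2 to 15.6 RPKM, Hspa8, the constitutive HSP70, from 825 to 684, Hspa1b from 47.9 to 34.5, Hsp90aa1 from 294 to 237 and Hspd1 from 94.1 to 79.8. Camera's adjusted p was 0.00207, and its adjusted p was 0.156 with an estimated correlation. Of 50 ribosomal protein genes, Rps14, Rpl13, Rpsa and Rpl12 fell (9 lower adjusted over the list alone), and the median was -0.08. The ribosomal list's adjusted p was 1.6e-06 by camera, 0.475 with an estimated correlation and 0.292 under quantile normalization. The fall of Hspd1 was lost without any naive library or memory 2 or 3, and those of the 4 ribosomal genes in at least 5 of the 6 fits that left out a library. The 13 mitochondrially encoded genes had no call, also adjusted over the list alone, and a median of -0.10. Their camera adjusted p of 0.0419 was lost with an estimated correlation (adjusted p = 0.602), under quantile normalization (0.522) and with the replicate number as a block (0.0678). It was also lost without naive replicate 1 or 2 or memory replicate 1 or 2 (0.0594 to 0.445).

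Cholesterol synthesis genes were higher, and all 19 tested had a positive change, with a median of 0.33. Of these, 6 rose and none fell (11 and 0 adjusted over the list alone). Cyp51 rose from 5.50 to 9.16 RPKM, Hmgcs1, an early enzyme of the pathway, from 13.5 to 20.1 and Idi1 from 6.36 to 8.60. The call of Idi1 was lost without any of the 6 libraries (adjusted p up to 0.109). Camera's adjusted p was 2.92e-08, and 0.0332 with an estimated correlation. The macrophage and monocyte list (median change 0.87) and the hepatocyte list (0.57) were higher in the same libraries. The other metabolic lists had few calls. Hk2 (0.30 to 1.11) was the only call among 22 glycolysis genes, Atp5b (197 to 170) the only one among 38 oxidative phosphorylation genes, and Cd36 (0.15 to 1.08) and Acaa2 (37.4 to 31.5) the only ones among 20 genes of fatty acid oxidation and lipid handling. Adjusted over the list alone, these lists had 2, 1 and 1 higher and 0, 1 and 2 lower members. Hk2 and Acaa2 lost the call without any library, Atp5b without any but memory 1, and Cd36 without naive 1 or 2 or memory 2 or 3.

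**Figure D3:**
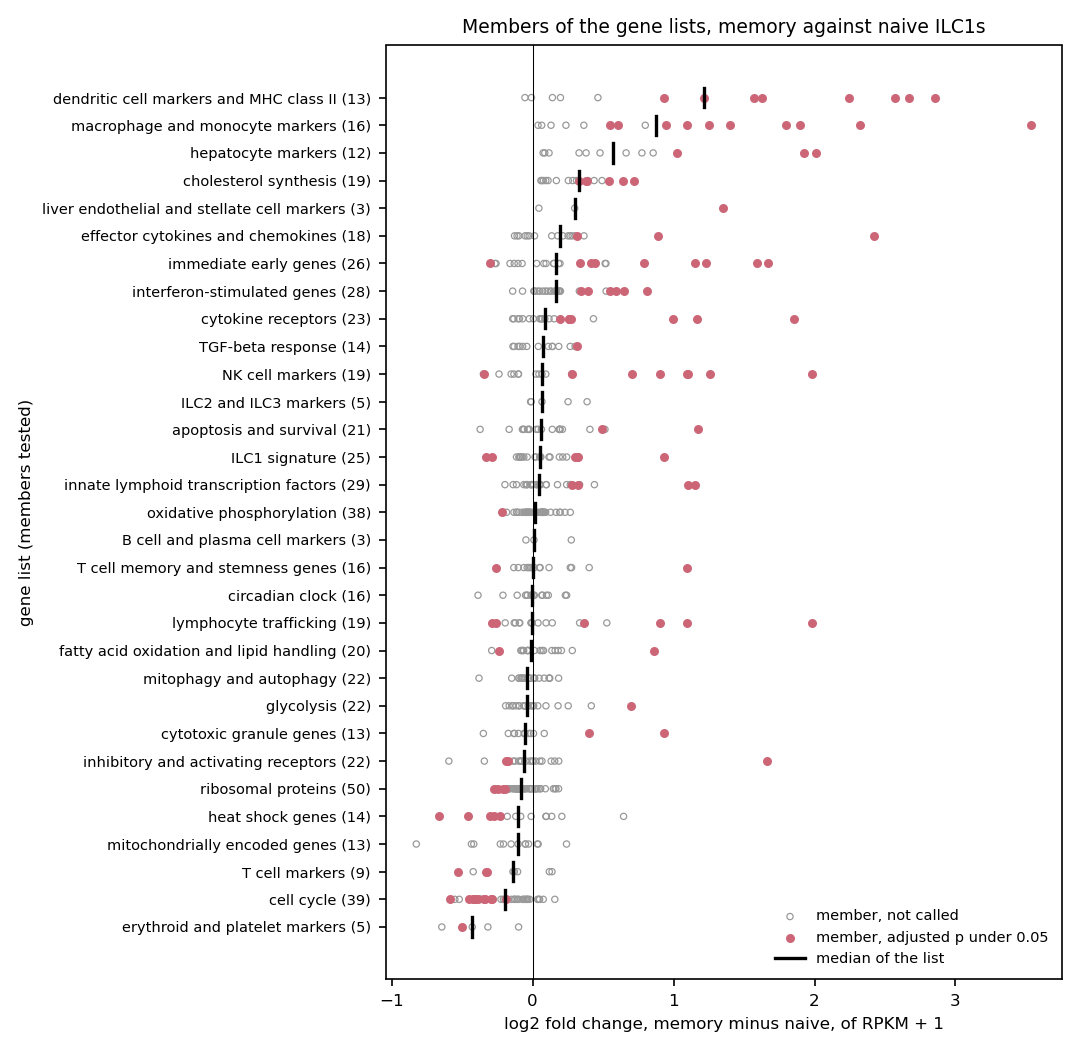
Log2 fold change, memory minus naive, of each tested member of the lists with at least 3 tested members. Filled points are called members, open points are members not called and black bars are list medians, which ran from -0.43 for erythroid and platelet markers to 1.22 for the MHC class II list.

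T cell markers were partly lower. Of 9 tested, 3 fell and none rose, also adjusted over the list alone. Tcrg-C1, a constant segment of the T cell receptor gamma chain, fell from 111 to 76.8 RPKM, Lat, a signalling adaptor, from 17.6 to 13.8 and Cd3g from 20.8 to 16.4, while the most abundant member, Trbc1, was at 192 and 174 and was not called. Lat lost the call without memory replicate 2 (adjusted p = 0.0532). The list's camera adjusted p was 0.000293, and the adjusted p was 0.137 with an estimated correlation. Of 12 hepatocyte markers, Apoe (39.8 to 154), Hp (0.69 to 5.79) and Alb (1.40 to 3.87) rose (6 and 0 adjusted over the list alone, camera adjusted p = 2.78e-06, and 0.039 with an estimated correlation). Apoe and Hp are also expressed by macrophages and monocytes, and Trf, the other abundant member, was at 21.8 and 23.2. Alb lost the call without any library but naive 3. Of 3 endothelial and stellate markers, Fcgr2b rose (0.27 to 2.27), a gene that myeloid cells share, and Pecam1 was at 14.9 and 18.6 (2 higher adjusted over the list alone, camera adjusted p = 0.0171, adjusted p = 0.156 with an estimated correlation). Hba-a2 fell (14.9 to 10.2) among 5 erythroid and platelet genes, whose most abundant member, Hbb-bs, was at 41.0 and 32.5 (4 lower adjusted over the list alone, camera adjusted p = 0.000293, adjusted p = 0.202 with an estimated correlation). Haemoglobin genes are near-identical copies, and Hba-a2 lost the call without any library but naive 3.

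The deepest falls were of structural RNAs. Rn7s1 and Rn7s2, copies of the 7S RNA of the signal recognition particle (chromosome 12, 69159295 to 69159594 and 69361182 to 69361481), fell from 418 ± 130 to 9.57 ± 1.27 and from 202 ± 42.4 to 0.83 ± 0.37 RPKM (log2 changes -5.27, SE 0.21, and -6.80, SE 0.18; adjusted p = 3.28e-05 and 1.11e-05). Rpph1, the RNA of RNase P (chromosome 14, 50807449 to 50807767), fell from 60.3 to 0.53 RPKM, with 363 to 404 reads in naive libraries and 0, 12 and 0 in memory libraries. Rprl3, a related sequence, had 35 to 38 reads in naive libraries and 0 in each memory library, at least 13-fold lower against a floor of 3 reads per library. These RNAs lack a poly(A) tail, and the 7S copies are near-identical to each other and overlap other annotated genes, so reads may be shared. Rn7sk, another short structural RNA, had 2 to 12 reads in each library of either group.

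The remaining lists showed no call as a set. The ILC2 and ILC3 markers (5 tested), the circadian clock (16), mitophagy and autophagy (22) and the B cell and plasma cell markers (3) had no called member, also adjusted over the list alone, and Ighm, the most abundant B cell marker, was at 85.0 and 85.4 RPKM. Of 14 TGF-beta response genes, Skil rose (9.52 to 12.1; 2 and 0 adjusted over the list alone), a call lost without any library. Of 16 T cell memory and stemness genes, 1 rose and 1, Cxcr3, fell (1 and 1 adjusted over the list alone). Camera's adjusted p for these 6 lists ran from 0.221 to 0.912, and for the glycolysis, oxidative phosphorylation, lipid and cytotoxic granule lists from 0.311 to 0.905. Camera's direction was lower in memory while the mean change was above 0 for the glycolysis (mean 0.02, median -0.04), cytotoxic granule (0.03, -0.06), lipid (0.05, -0.01), oxidative phosphorylation (0.02, 0.02) and T cell memory (0.10, 0.00) lists, and higher while the median was -0.01 for the trafficking list. In all, 16 of 31 lists were past camera's threshold, and 5 with an estimated correlation. Fry differed for some lists. The NK cell, apoptosis, transcription factor and trafficking lists were higher by fry only (fry adjusted p = 0.000478, 0.0104, 0.0128 and 0.0128). The inhibitory and activating receptor, ribosomal and mitochondrially encoded lists were past camera's threshold only (fry adjusted p = 0.186, 0.19 and 0.477).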

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

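None of the 575 calls changed sign under any alternative that tested it. The total was 404 to 595 under the other pseudocounts, filters, scalings, prior and weights, with 286 higher at a mean of at least 2 RPKM, where fewer genes were tested, and 87 lower with no filter, where more were. Voom on the recovered reads gave 1141 calls (794 higher, 347 lower), and an added absolute log2 fold change of at least 1 left 181 (166 and 15). With fewer libraries the totals were 275 to 387, with 234 to 310 higher and 41 to 77 lower. The replicate number as a block gave 271 calls (229 and 42), of which 258 were among the 575. Of the 103 genes named in the text that the main fit called, at most 67 kept the call with that block. Same-numbered libraries did not deviate together (correlations -0.084, -0.04 and -0.003), so no shared effect of the number was visible. The labels do not say whether equal numbers share an animal or day, and these correlations cannot settle it. After seeing the data, restriction to protein coding genes gave 757 calls and removal of the lists of other cell types 534. That removal dropped listed genes only, so unlisted genes of those cell types stayed among the 13731 tested. With an estimated correlation, 5 of the 31 lists stayed past the threshold in place of 16. Apart from the smaller designs and filters, the cause was not tested. Over all alternatives, the 124 genes that the text names gave 2184 values, of which 1939 kept direction and side of the threshold, 226 lost the call, 10 gained it and 9 changed sign, all 9 of genes that were never called. The 40 genes that the rule took and the text leaves out gave 704 values, of which 30 gained the call and 14, of 4 genes never called, changed sign. Among the genes of the text the sign changes were in Itga2 (-0.016 under quantile normalization, -0.007 with array weights, -0.075 to 0.092 with a library left out, below 0 without memory replicate 3 or naive replicate 1), Tbx21 (-0.043 to 0.036, above 0 without those libraries), Ighm (-0.009 under median ratio scaling, -0.06 to 0.045 with a library left out, below 0 without naive replicate 3) and Klrb1c (0.016 under quantile normalization). Camera's direction turned for lists never past the threshold: T cell memory (adjusted p = 0.986 under quantile normalization, 0.74 to 0.944 with a library left out, turned without memory replicate 1 or naive replicate 1), lipid handling (0.688 to 0.961, turned without naive replicate 1 or 2 or memory replicate 3), trafficking (0.562 to 0.928, turned without naive replicate 3) and oxidative phosphorylation (0.91 under quantile normalization). Depth limits genes near the floor of 0.126 to 0.16 RPKM per kilobase of exon, and the simulation recovered 69.4% of 2-fold changes.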

Other observations

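The 6 lists of these opening paragraphs, and every test below except the spread of the macrophage list between memory libraries and the count of splits, were chosen only after the results were seen. Genes of the NF-kB pathway were higher in memory. All 26 tested members had a positive change, and 11 rose and none fell, with a median of 0.23. Icam1, an adhesion molecule that NF-kB induces, rose from 35.8 to 61.4 RPKM, Nfkb2 from 19.3 to 31.9 and Relb from 5.06 to 7.90, the last not called without naive replicate 3 or any memory library (adjusted p up to 0.0673). Of 18 GTPases induced by interferon-gamma, 8 rose and none fell, among them Tgtp1 (21.9 to 30.5), Gbp10 (12.4 to 18.6) and Iigp1 (2.31 to 4.97). Iigp1 lost the call without memory replicate 2 or 3. Both lists hold members of the fixed lists (Nfkbia, Birc3, Gbp3), so they add to those only in part. Myeloid cells express genes of both lists too, and in the same libraries the macrophage and monocyte list had a median change of 0.87 and the MHC class II list 1.22.

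Co-chaperones of HSP90 and chaperonin subunits were lower, with 6 of 21 tested members down, none up and a median of -0.12. Stip1 fell from 139 to 100 RPKM, St13 from 133 to 110 and Fkbp4 from 69.6 to 57.2, the last not called without memory replicate 2 or 3. Replication genes beyond the fixed cell cycle list fell in 10 of 38 cases and rose in none, for example Clspn (8.41 to 5.21) and Lig1, the ligase of the lagging strand (30.2 to 21.6). Of 12 genes of classical monocytes, 9 rose, for example Fn1 (1.12 to 10.2) and Chil3 (0.37 to 4.02), and of 14 genes of non-classical monocytes 9 rose, for example Ace (0.83 to 6.22) and Ceacam1 (0.34 to 5.18). The neutrophil genes S100a8 and S100a9 had 0 to 6 reads in every library. Camera's adjusted p over the 6 lists ran from 9.66e-16 to 9.24e-10, and from 0.0043 to 0.0135 with an estimated correlation. Being picked from the same libraries, these lists are no independent evidence of direction.

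Macrophage and monocyte genes were higher in memory. If resident Kupffer cells alone had brought them, the 6 Kupffer cell members of the list would have risen by at least as much as the 10 others, but their median log2 ratio of mean RPKM, taken without a pseudocount, was 0.40 against 2.29 (difference -1.898, exact one-sided permutation test across genes, p = 0.026), although Marco, among the 6, rose from 1.18 to 7.01 RPKM. Genes are not independent replicates, so the p-value of that permutation test may be too small. The list's mean varied between memory libraries no more than that of random lists (percentile 32.5 of 10000 lists matched on mean expression). A share of other cells that varied between these libraries was thus not seen. A share common to the memory libraries would give the same result, and the labels do not say whether replicates came from separate animals. The spread therefore cannot decide whether other cells were present. A larger share of monocytes or macrophages in the memory samples cannot be told apart from expression of these genes by memory ILC1s themselves, since all 16 tested members lay above 0, as either would give. Lyz2 stood at 448 RPKM and Cd74 at 122 in memory. Ccr2, one of the 16, is also made by ILC1s, and no sort or gate is given that would remove such cells.

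7S RNA and RNase P RNA were lower in memory. The 284 tested snoRNA, snRNA, scaRNA and rRNA genes had a median log2 change of 0.216 (bootstrap interval 0.143 to 0.31), so as a group they did not fall. A lower yield of all short non-coding RNAs would have lowered that median. The median cannot decide this, because genes so short can pass the filter of 0.5 RPKM on few reads, with little room to fall. A difference between naive and memory cells in 7S RNA and RNase P RNA, or in how their libraries were made, was not tested and stays open.

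Cell cycle genes were lower in memory. Dilution of lymphocyte RNA by other cells, as the only cause, would lower the receptor genes of lymphocytes alike. The median change of the 39 cell cycle genes lay below that of 22 inhibitory and activating receptor genes (difference -0.133, one-sided permutation test across genes, p = 0.0052), and genes are not independent replicates. The receptor median was itself below 0 (-0.064), and that list holds Havcr2, also on myeloid cells, which rose. Dilution as a part of the fall therefore stays open. Less division in memory than in naive cells stays open, as does a change in which cells were captured.

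For the count of calls, 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave 575 genes and the highest of the others gave 0. With 10 splits the share cannot fall under 0.1, too few to say more.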
